A study of Mus musculus with 2 samples.

How the data were processed

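Dissociated cells from dorsal root ganglia of mice at postnatal day 4 were profiled by droplet-based single-cell RNA sequencing of transcript 3′ ends. There were 2 libraries. One came from Ptges3 flox/flox mice without Cre (Flox control) and the other from Ptges3 flox/flox mice carrying Dhh-Cre (Ptges3 cKO). Per the labels' protocols, actinomycin D was present from dissection (30 µM) through digestion (15 µM), dissociation (3 µM) and resuspension (0.3 µM) to block new transcription. The labels' protocols also give a target of 10000 cells per sample and 12 cycles of cDNA amplification. How many animals contributed to each library is not given in the sources used here.

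The deposited matrices hold counts, as whole numbers of UMIs per feature row and barcode, with no normalization in the values. Per the file headers, both matrices were written by Cell Ranger 7.0.0, whereas the submitters' processing notes name Cell Ranger 5.0.1, Scanpy and the mm10 build. The versions can differ in which reads they count, and the reason for the mismatch is not given in the sources used here. No barcode in either matrix had fewer than 500 UMIs, so barcodes below that level had been removed before deposit. Each matrix had 32285 feature rows, identified by row number only. No table pairing these rows with gene names was used here, and rows were not matched to an annotation by their order. Consequently genes are called features and are given by row number, and clusters carry numbers in place of cell type names. The level of Ptges3 was not analysed here. Counts of 3′ ends would check the genotype labels only where they fall in the deleted part. The mitochondrial filter was not applied, and the cell type markers and gene lists fixed in advance were not used.

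Before the data were examined, the filters, the clustering, the count and fold thresholds, the rule for named features and the first set of alternatives were fixed. Barcodes with at least 500 detected features were kept. Doublets were scored in each library by the Scrublet method, rewritten with exact nearest neighbours, with 2 simulated doublets per cell and an expected rate of 5%. Its automatic threshold marked 0 of 41248 Flox control barcodes and left out 1 cKO barcode. A share this far under 0.5% means that the caller did not work on these data, so doublets remain in every value below. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable features were scaled, with values limited to 10, and reduced to 30 principal components. Cells of both libraries were clustered together on a graph of 15 shared nearest neighbours with the Leiden algorithm at resolution 1.0 (igraph 0.11.9), without batch integration. The resulting clusters are numbered C1 to C36. A second clustering, added after the data were seen, left features at least 1.5-fold apart between the libraries out of the variable features. Its clusters are numbered S1 to S27 and are called shared-feature clusters.

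For each comparison, counts were summed over the cells of a library, or over its cells in 1 cluster, and divided by their total and scaled to 1000000 (CPM). The ratio of cKO over Flox control was taken on the log2(CPM + 1) scale, which understates the change of features near or under 1 CPM. A feature was measured where its summed count was at least 100 in at least 1 library. Clusters with at least 100 cells in each library were compared. The named features are the 2 with the highest and the 2 with the lowest ratio over all cells, among features with at least 50 CPM and a summed count of at least 100 in at least 1 library. Intervals are 95% intervals: exact Poisson for summed counts, exact Clopper-Pearson for shares, and exact conditional binomial for ratios. They cover counting error only. There was 1 library per group, so no test of genotype was made and no p-value is given. Differences describe these 2 libraries.

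The comparison was tested on simulated data of 32285 features with 200 changed by 3-fold and counting error alone. The 200 were drawn only from features with an expected count of at least 100 in both libraries. Over all cells, 84% of the changed features were recovered as at least 2-fold apart, and 100% of the 142 changed features at or above 5 CPM. In cluster S23, the compared cluster with the fewest cells in a library, 100% were recovered. All 200 lay at or above 5 CPM there, so recovery was nearly assured. Clusters with fewer UMIs were not simulated, such as S21 with 501728 in the Flox control against 1767713 in S23. In both simulations 0 unchanged features passed the threshold, and the intervals held the true ratio for 94.5% of measured features. To compare detected features per cell at equal depth, each cell was also thinned to 1000 UMIs, leaving out 1009 shallower cells of the Flox control and 1068 of the cKO. Alternatives were other detected-feature minimums, clustering resolutions, scalings (a trimmed mean of M values and a median of ratios), equal weight per cell, count filters, pseudocounts and fold thresholds, thinning before clustering, and keeping called doublets. Removal of the highest 10% of doublet scores, thinning the larger library's summed counts to the total of the smaller, and clustering thinned cells on shared features were added after the data were seen, as were the sums over deep clusters, meaning those with a median of at least 7000 UMIs in each library. The leading features of a cluster are the 10 with the highest ratio of its level to that in all other cells, with 10 CPM added to each. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-image 0.26.0.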

Results

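The study addressed how prostaglandin E2 from Schwann cells acts on developing sensory neurons. Ptges3 encodes a cytosolic prostaglandin E synthase that is also known as the Hsp90 co-chaperone p23, and Dhh-Cre is active in the Schwann cell lineage. The comparison here is between ganglion cells of 1 Ptges3 cKO library and 1 Flox control library, both from mice at postnatal day 4. The level of Ptges3 was not analysed here, so the genotypes are those of the labels. The dorsal root ganglion holds the cell bodies of sensory neurons with their satellite glia, Schwann cells, vessels and connective tissue.

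The Flox control matrix held 41531 barcodes and 181515457 UMIs, and the cKO matrix held 33778 barcodes and 136415812 UMIs. These barcode numbers are 4.15 and 3.38 times the stated target of 10000 cells per sample. After the detected-feature filter, 41248 Flox control cells (99.3% of barcodes) and 33550 cKO cells (99.3%) remained. The median cell had 3233 UMIs in the Flox control (quartiles 2158 and 5022) and 2798 in the cKO (quartiles 1853 and 4649). Median detected features per cell were 1868 and 1667. With every cell thinned to 1000 UMIs, the medians were 747 features in 40239 Flox control cells and 745 in 32482 cKO cells. In the same cells without thinning they were 1895 and 1700. Cells with at least 10000 UMIs made up 5.54% of Flox control cells (95% interval 5.32 to 5.76%) and 6.50% of cKO cells (6.24 to 6.77%).

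**Figure D1:**
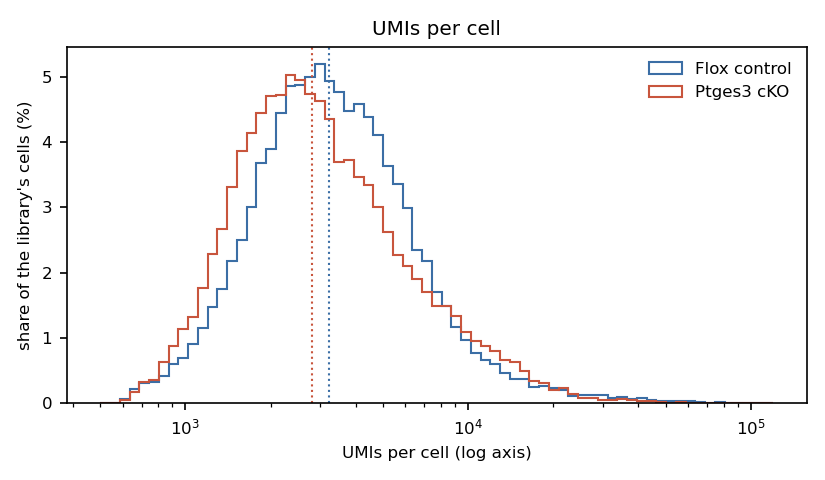
Distribution of UMIs per cell in each library. The x axis is UMIs per cell on a log scale, the y axis is the share of the library's cells in percent, and dotted lines mark the medians of 3233 (Flox control) and 2798 (cKO).

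The first question is whether the ganglia of both libraries held the same cell populations. In the clustering as designed, some of the most populous clusters came mainly from 1 library. Cluster C1 held 34.5% of cKO cells and 1.65% of Flox control cells, whereas cluster C3 held 19.7% of Flox control cells and 1.64% of cKO cells. Of their 10 leading features, 7 in C1 and 1 in C3 were themselves at least 2-fold apart between the libraries within the cluster. Across the 36 clusters, the compositions of the libraries differed by 59.7 percentage points, the share of cells that would have to change cluster for them to match. It was 29.6 points at Leiden resolution 0.5 and 26.8 points with every cell thinned to 1000 UMIs, so its size depended on the clustering. Of those 36 clusters, 16 came to over 90% from 1 library at equal library weight. They held 60.6% of Flox control cells and 51.8% of cKO cells. The difference was 20.3 points across the 27 shared-feature clusters, which were chosen after the data were seen and made without features 1.5-fold apart between libraries. Leaving out such features lowers the difference in part by construction. It can also remove the features that mark a population whose share differed. Shares are compared below in the shared-feature clusters, and neither clustering settles whether the libraries held the same populations.

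Of 22 shared-feature clusters with at least 100 cells per library, 18 had no leading feature that was 2-fold apart. Of these 18, 12 held a larger share of the cKO library and 6 a larger share of the Flox control. The interval of the ratio included 1 for S6 and S8 of the 12 and for S7 of the 6. Shares add up to a whole, so a lower share of some clusters raises that of others. Clusters S12, S17, S20 and S23, each with a median of at least 7000 UMIs in both libraries, held 3.01 to 4.14 times as large a share of the cKO library. S12 held 4.48% of cKO cells (95% interval 4.26 to 4.70%) and 1.49% of Flox control cells (1.37 to 1.61%). S20 held 1.77% of cKO cells (1.63 to 1.91%) and 0.427% of Flox control cells (0.366 to 0.494%). S17 held 1.97% against 0.609%, and S23 0.996% against 0.252%. Summed, these 4 clusters held 9.21% of cKO cells (8.91 to 9.53%) and 2.78% of Flox control cells (2.62 to 2.94%). The cKO cells in them were the shallower ones, with median UMIs of 12208 against 19893.5 in S20 and 8143 against 16347 in S23.

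Cluster S5 went the other way. It held 8.12% of Flox control cells (7.86 to 8.39%) and 1.12% of cKO cells (1.01 to 1.24%), a share 7.27 times as large in the Flox control (6.53 to 8.11). S5 also had many UMIs per cell in the Flox control, with a median of 6526 against 3792 in the cKO. When every cluster with a median of at least 6000 UMIs in either library was summed, the shares were 11.3% in the Flox control and 12.1% in the cKO. The larger cKO share therefore held for S12, S17, S20 and S23 and depended on which clusters were summed. When thinned cells were clustered on shared features, the 4 clusters holding most cells of S12, S17, S20 and S23 in either library took in 15.2% of cKO cells and 8.41% of Flox control cells. They were largely other cells, since cells of S12, S17, S20 and S23 made up 40.3% of them in the cKO and 22.1% in the Flox control. S4 was also larger in the Flox control, at 6.44% against 4.08%. The 2 most populous clusters, S1 and S2, held 22.5% and 22.8% of Flox control cells and 18.4% and 17.5% of cKO cells.

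S6 held 4.44% of Flox control cells and 4.49% of cKO cells, a cKO over Flox ratio of 1.01 with an interval of 0.945 to 1.08. S8 held 3.89% and 3.90%, with a ratio of 1.00 (0.930 to 1.08), and S7 held 4.06% and 3.78%, with a ratio of 0.931 (0.865 to 1.00). S15 held 1.95% of cKO cells and 0.977% of Flox control cells, and S18 held 1.64% and 0.793%. S11 had a ratio of 1.71 (1.57 to 1.86). With 1 library per group, these intervals leave out the variation between animals and dissections.

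**Figure D2:**
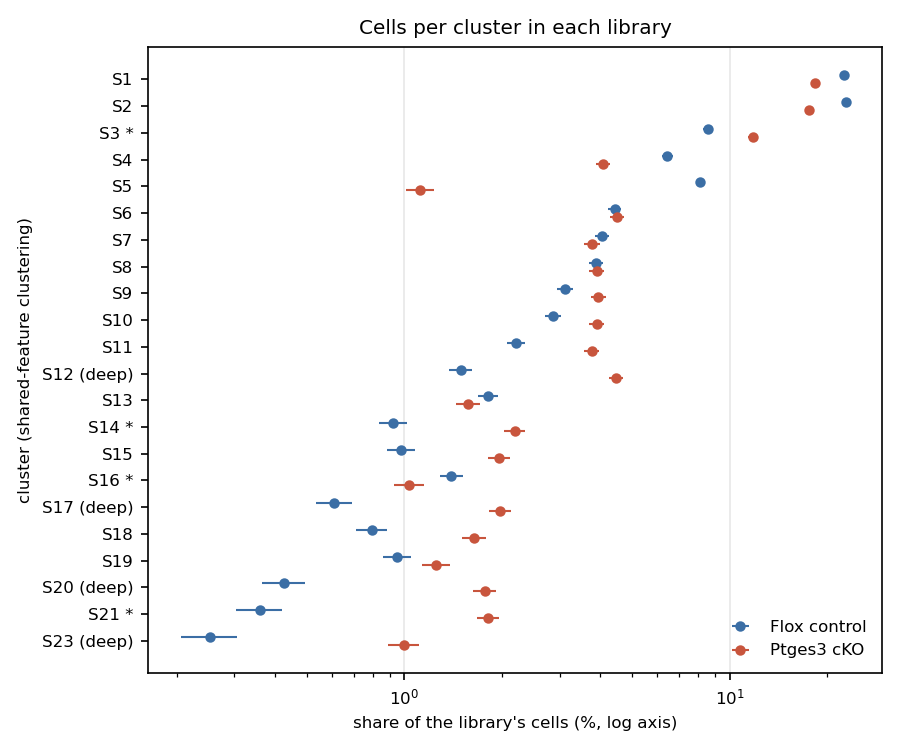
Share of each library's cells (percent, log axis) in the 22 shared-feature clusters compared, with 95% Clopper-Pearson intervals as bars, which cover counting error only. The 4 clusters marked deep have medians of at least 7000 UMIs in each library and all lie at larger shares in the cKO, S5 lies far to the right in the Flox control, and asterisks mark 4 clusters with leading features that are 2-fold apart.

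The second question is which transcripts differed between the libraries. Over all cells, 16576 features were measured, and 84.7% of them lay within 1.2-fold between cKO and Flox control with 1 CPM added. Adding 1 CPM draws features near or under 1 CPM toward equality, which raises this share. The log2(CPM + 1) values of the libraries correlated across features with r = 0.991, where features are not independent replicates. At least 2-fold apart were 200 features, 1.21% of those measured, of which 128 were higher and 72 lower in the cKO. With a pseudocount of 10 CPM in place of 1, the numbers were 17 higher and 19 lower. With each cell weighted equally, 199 were higher in the cKO.

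A pair of features was found almost exclusively in 1 library. Feature 31061 had 141329 counts in the Flox control (779 CPM, 95% interval 775 to 784) and 19 in the cKO (0.139 CPM, 0.0840 to 0.218). It was higher in the Flox control in all 22 compared clusters, with cluster levels of 214 to 2211 CPM there and at most 5 counts in any cKO cluster. Feature 31481 showed the mirror image. It had 11701 counts in the cKO (85.9 CPM, 84.3 to 87.4) and 37 in the Flox control (0.204 CPM, 0.144 to 0.281). Its cluster levels in the cKO were 57.3 to 113 CPM, in all 22 clusters, against at most 10 counts in any Flox control cluster.

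The other 2 named features differed less and varied more between clusters. Feature 12664 was at 54.6 CPM in the cKO (53.4 to 55.8) and 4.34 CPM in the Flox control (4.04 to 4.65), 12.6 times as high (11.7 to 13.6). With 1 CPM added to each level, which lowers the ratio, its log2 ratio was 3.38, and 4.13 with each cell weighted equally. It was higher in the cKO in all 22 clusters and at least 2-fold higher in 21, the exception being S20. Feature 16829 was at 76.7 CPM in the Flox control (75.4 to 78.0) and 7.79 CPM in the cKO (7.33 to 8.28), 9.84 times as high in the Flox control (9.24 to 10.5). It was lower in the cKO in all 22 shared-feature clusters and at least 2-fold lower in 19. In the clustering as designed, cluster C5 held 7421 of its 13906 Flox control counts and 372 of its 1062 cKO counts, at 458 and 356 CPM. That clustering did not leave out features that differed, so C5 may group cells by this RNA itself. Whether C5 does so was not tested. The nearness of these levels therefore does not separate a difference in level from a difference in the number of cells holding this RNA. C5 comprised 12.0% of Flox control cells and 1.15% of cKO cells. In S9 the levels were 49.9 CPM in the Flox control and 35.6 CPM in the cKO. Each of these 2 features peaked in a small cluster that was too unevenly filled to compare, 16829 at 3605 CPM in S24 of the Flox control and 12664 at 921 CPM in S22 of the cKO.

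**Figure D3:**
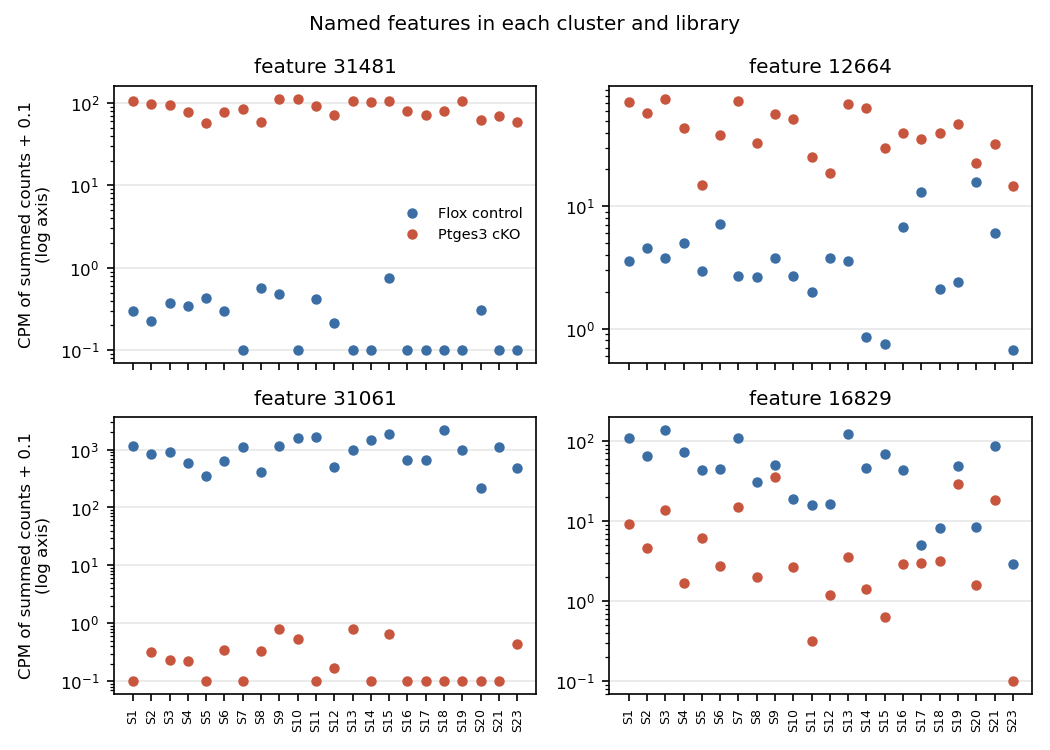
Level of the 4 named features in each of the 22 shared-feature clusters, as CPM of summed counts plus 0.1 on a log axis, 1 point per library and cluster. Features 31061 and 31481 are separated by library in every cluster, whereas the library levels of 12664 and 16829 lie closer and shift with the cluster.

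Within clusters, the minimum of 100 counts is a higher level in CPM than over all cells. The shares of features apart are therefore not directly comparable between the 2, and they ran from 0.396% in S9 to 6.38% in S21. Over the 22 shared-feature clusters, a median of 66 features per cluster was at least 2-fold apart, which was 1.16% of those measured. The number ran from 25 in S13 to 499 in S21. S21 joined cells of unlike depth, with medians of 3033 UMIs in the Flox control and 9390.5 in the cKO, and of its features 171 were higher and 328 lower in the cKO. More features were higher than lower in the cKO in 16 clusters, and the reverse held in 6. In the clustering as designed, these numbers were 13 and 10. A feature needed 100 counts in either library to be measured, which favours the library with more UMIs in a cluster. With the larger library of each cluster thinned to the total of the smaller, more features were higher in 17 shared-feature clusters and lower in 4, and the median was 50 features apart. The same thinning in the clustering as designed gave more higher in 16 clusters, more lower in 6 and 2 tied. S20 then had 67 features higher and 5 lower, against 111 and 5 without thinning, and S12 had 74 and 12, against 101 and 13. S5 turned from 84 higher and 132 lower to 12 and 8, and S21 came down to 5 higher and 36 lower. Fewer features were then measured, 3458 against 11969 in S5 and 911 against 7817 in S21, so part of each fall is in features measured. With a summed count of at least 500, the median cluster of the clustering as designed had 4.5 features higher and 5 lower, against 33 and 15 with 100.

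Of 1268 features at least 2-fold apart in at least 1 cluster, 922 were apart in exactly 1 cluster, and 37 went in opposite directions in different clusters. Among 8171 features measured in at least 10 clusters, 883 were apart in at least 1 cluster, 670 of them in exactly 1 and 213 in at least 2. Of these 8171, 20 were at least 2-fold higher in the cKO in at least 50% of the clusters where measured, and 14 were at least 2-fold lower. For the 1895 features measured in all 22 clusters, the log2 ratios of cluster pairs had a median correlation of 0.740 across features, with a range of 0.0848 to 0.973. That value rests in large part on the named features among them. Over the 1893 features left without these, the median was 0.490 and the range -0.316 to 0.907. A total of 328 features were lower in 1 to 5 clusters and within 1.2-fold in most others, and 244 were higher in that manner.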

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

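With 1 library per group, no paired analysis was possible and no library could be left out in turn. Without gene names, alternatives for Ptges3, the gene lists and the mitochondrial maximum were not run. The tests without the highest 10% of doublet scores, without features 1.5-fold apart, at equal totals and on deep clusters were chosen after the data were seen. Cells kept moved from 99.3% of barcodes in each library to 99.95% (Flox control) and 99.99% (cKO) with a minimum of 200 features, to 90.3% and 86.0% with 1000, and to 89.4% in both without the highest 10% of doublet scores. Median UMIs became 3481 and 3137 with the minimum of 1000 features, and 3079 and 2627 without the highest doublet scores. The composition difference of 59.7 percentage points became 67.1 with the minimum of 200 features, 71.3 with 1000, 67.9 with called doublets kept, 64.8 without the highest doublet scores, and 29.6 and 68.1 at Leiden resolutions 0.5 and 2.0. It was 26.8 with cells thinned before clustering, 20.3 without the features that were 1.5-fold apart, and 16.7 with both. Keeping called doublets added only 1 cell, so differences of that size arise from the clustering itself, and the cause of the larger ones was not tested. The summed share of the deep clusters stayed larger in the cKO in all 10 clusterings, by 2.67 to 4.23 times, but with the bound at 6000 UMIs in either library it was 9.90% in the Flox control and 9.52% in the cKO of the clustering as designed. Over all cells, the 128 features higher in the cKO became 199 with equal weight per cell, 17 with a pseudocount of 10 CPM and 419 at 1.5-fold, and the 72 lower became 19 and 173 with the last 2. The median cluster of the clustering as designed had 33 features higher and 15 lower. These became 269.5 and 108.5 with a summed count of at least 20, 4.5 and 5 with 500, 705 and 439 with no filter, 15.5 and 9 with the pseudocount of 10 CPM, 182 and 92 at 1.5-fold, and 12.5 and 9.5 with the larger library of each cluster thinned to the total of the smaller. Lower filters admit weaker features and the larger pseudocount shrinks their ratios, by construction. The other 39 values for cells, depth and feature counts stayed within counting error or 1.5 times. Over all cells, lower filters could not move 128 and 72, since 1 CPM added keeps features under 100 counts within 2-fold. Keeping called doublets there added only 1 cell. Rescaling moved log2 ratios of cKO over Flox control without a pseudocount by -0.05 (trimmed mean of M values) and -0.06 (median of ratios). Those with the pseudocount moved less. The 4 named features had the same direction under each of 7 alternatives, but their log2 ratios ran from 3.23 to 6.28 (31481), 2.17 to 4.13 (12664), -9.69 to -6.28 (31061) and -3.21 to -2.28 (16829), and each was nearest to 0 with the pseudocount of 10 CPM.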

Other observations

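The tests in this part were chosen after the results were seen. Among small clusters, S22 held 1.85% of cKO cells (95% interval 1.70 to 1.99%) and 0.0824% of Flox control cells (0.0571 to 0.115%), and S25 held 0.471% and 0.104%. S24 and S26 were larger in the Flox control, at 0.441% against 0.155% and at 0.313% against 0.0328%. These clusters had fewer than 100 cells in 1 library and were not compared further.

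Features 31061 and 31481 were present throughout 1 library and nearly absent from the other. Free RNA from 1 cell population among the clusters would leave that cluster far above the rest. The highest cluster was only 2.36 times the median cluster for feature 31061 in the Flox control and 1.68 times for feature 31481 in the cKO, which argues against free RNA of 1 cluster as the origin of either. Both were found in each compared cluster of their library, at 214 to 2211 CPM for 31061 and 57.3 to 113 CPM for 31481, and a difference between the animals, such as sex, strain background or the genotype, may be present. With 1 library per group, these cannot be told apart, and the features' names were not used here.

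Feature 16829, at 3605 CPM in S24 of the Flox control against 45.6 CPM in the median cluster, belongs to 6 features that were at least 2-fold lower in the cKO and lead S24. Outside S24, these 6 summed to 863 CPM in the Flox control and 127 CPM in the cKO, and their mutual proportions differed from those in S24 by a median of 2.59 percentage points over 19 Flox control clusters, with 1 cluster as far as 21.1. Such near-constant proportions would also arise from RNA of S24 carried into other cells. S24 cells were 2.85 times as frequent in the Flox control and the level outside S24 was 6.80 times as high there. Frequency alone does not give the RNA held in S24, so the smaller ratio of frequencies does not argue against carried RNA. Its Flox control cells also had more UMIs (median 3035.5 against 1548) and a higher level of the 6 features (46739 against 30438 CPM). Of the counts of these features, 82.5% in the Flox control and 87.0% in the cKO lay outside S24. S24 thus held no smaller a part of them in the Flox control. Their amount in S24 was therefore lower in the cKO by at least as large a factor as their level outside. RNA carried from S24 could account for the difference outside it, and a difference in expression was not separated from this. Feature 16829 was not spread evenly, at 2.83 to 139 CPM over the 22 compared shared-feature clusters of the Flox control. It was lower in the cKO in all 22. C5 of the clustering as designed (12.0% of Flox control and 1.15% of cKO cells) held 7421 of its 13906 Flox control counts at 458 CPM, against 356 CPM in the cKO. That clustering kept features that differed, so C5 may group cells by this RNA. A UMI of it was found in 13.1% of Flox control cells and 1.41% of cKO cells, but a lower level also leaves fewer cells with a UMI. A difference in how many cells held it is therefore not separated from a difference in level. For feature 12664, which reached 921 CPM in S22 of the cKO, the same comparison over 5 features gave a median of 12.0 points and 1 cluster as far as 43.8, which decides nothing, and a genotype difference in expression stays open for both features.

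The clusters S12, S17, S20 and S23 held larger shares of the cKO library. The ratio of their summed shares was 3.32, and it was 1.81 in the clusters of thinned cells that held most of their cells. Those clusters took in only 65.4% of these cells in the Flox control and 64.6% in the cKO. Cells from S12, S17, S20 and S23 made up only 22.1% of them in the Flox control and 40.3% in the cKO. The fall in the ratio therefore does not measure a part due to depth. For the deep clusters of that clustering of thinned cells, the ratio was 2.67 (2.46 to 2.88), and the Flox control was the deeper library (median 3233 against 2798 UMIs). Different depth of the libraries was not separated by this test and stays open. Without the cells of the highest 10% of doublet scores the ratio was 3.24, but the doublet caller did not work on these data, so doublets stay open too. Loss of these cells during dissociation of the control ganglia, sampling of different ganglia and the genotype also remain possible and untested, and no explanation was tested for the 7.27 times larger share of S5 in the Flox control.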
